A study of Mus musculus with 16 samples.

How the data were processed

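RNA was measured in forebrain tissue of 16 female mice aged 6 to 7 months, with 1 array per sample. The cerebellum had been taken off and the forebrain split down the midline before freezing, per the labels' protocols. RNA was isolated with TRIzol and a column, and biotin-labelled cDNA was made from 100 ng of it for Affymetrix whole-transcript arrays, per the labels' protocols. The labels also call the tissue whole brain. The mice form 4 groups of 4 by genotype: WT_WT, WT_5xfAD, Rag_WT and Rag_5xfAD. The 5xfAD line carries transgenes with familial Alzheimer's disease mutations, driven by the Thy1 promoter. Arrays labelled Rag come from mice lacking Rag2 and Il2rg, which have no T cells, B cells or NK cells. Groups and replicate numbers were taken from the genotype and title labels.

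The deposited values are log2 expression values, 1 per transcript cluster, and the submitters' processing notes name RMA and the oligo package without versions. RMA corrects background, equalises the distributions of the arrays and summarises the probes of each transcript cluster. The genome build and any further step are not given in the sources used here. Scanner files were not used here, so signal over background, slide and scan date were not analysed here, and the number of arrays limits the precision. The table holds 24600 transcript clusters with values from 1.91 to 13.86 and 0 missing values. Array medians lay between 6.77 and 6.88, and Pearson correlations between arrays, across transcript clusters, lay between 0.991 and 0.998. The interquartile range still differed between groups after the authors' normalization: it averaged 2.55 ± 0.05 (SD, n = 4) in WT_WT, 2.62 ± 0.02 in WT_5xfAD, 2.65 ± 0.04 in Rag_WT and 2.76 ± 0.04 in Rag_5xfAD. For this reason the split of higher and lower calls is also given after a further normalization where the share of higher calls moved by over 10 points.

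Gene names came from the platform annotation, which gives exactly 1 symbol for 22308 transcript clusters, several for 860 and no entry for 1432. Clusters with several symbols were not named. Symbols were updated through Entrez numbers with the RefSeq gene table of the GRCm38.p6 assembly, which held 22059 of the one-symbol clusters and changed 807 symbols. No coordinates are printed, since the build of the array design is not given in the sources used here, and the RefSeq table served only for names and for the order of neighbouring genes. Of several clusters of one gene, the one with the highest mean over all arrays was kept, which concerned 200 genes and left 22067 genes for testing with no filter on level. Values identical to those of another cluster to 6 decimals occurred in 205 clusters. Il2rg was not analysed here, since no cluster carried its symbol alone.

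Log2 fold changes, their standard errors and p-values came from limma 3.58.1 in R 4.3.3. One mean per group was fitted to all 16 arrays, the variances were moderated with eBayes, and p-values were adjusted over all 22067 genes by the Benjamini-Hochberg method with a threshold of 0.05. The 5 comparisons were WT_5xfAD minus WT_WT, Rag_5xfAD minus Rag_WT, Rag_WT minus WT_WT, Rag_5xfAD minus WT_5xfAD, and the interaction, which is the transgene effect in immune-deficient mice minus that in immune-competent mice. The p-values of limma measure the spread between mice. Those of camera compare genes of a list with other genes at a given correlation, and permutation p-values from random gene lists rest on draws of genes. An adjusted p below is limma's unless another test is named.

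Before the data were examined, 37 gene lists were fixed from textbook knowledge, none of them chosen on these samples. They cover lymphocytes, microglial states, complement, antigen presentation, interferon and cytokine genes, glia, neurons, vessels, tissue outside the intended dissection, lipid and lysosomal genes, stress, respiration, ribosomes and the neighbours of both targeted genes. Of their 638 members, 549 were measured. The 34 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation and with fry. The targeted genes, the transgene-related genes and the red blood cell genes were too few for the list test. Of their 1, 2 and 4 measured members, Thy1 passed in both transgene comparisons and Rag2 in Rag_5xfAD against WT_5xfAD. Some lists share members, among them Trem2, Cd68 and Apoe. For lists past camera, the count of members past the threshold is given over all genes and adjusted over the list alone.

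The genes named in the text follow a rule fixed before the data were examined. It takes Rag2, App and Thy1 in every comparison, up to 8 genes with the largest rise and 8 with the largest fall among genes past the threshold whose groups do not overlap, and up to 4 members of each list with the smallest p. Where fewer than 3 genes passed, the 3 with the smallest p are given as values. Genes outside the rule are said to have been chosen after their values were seen.

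The fits and list tests were tested on simulated arrays with the observed means and variances and 200 changed genes. The noise was drawn independently for each gene. These arrays thus held no correlation between genes and no trend with level, and cannot show how the fits and camera behave under either. At a true log2 change of 0.5 they recovered 100% of the changed genes for WT_5xfAD against WT_WT, 97.0% for Rag_5xfAD against Rag_WT, 98.5% for Rag_WT against WT_WT, 92.5% for Rag_5xfAD against WT_5xfAD and 76.1% for the interaction. At a true change of 0.25 the shares were 61.2%, 53.7%, 58.2%, 62.7% and 19.4%, in that order. Alternatives tried were filters on level, quantile normalization of the tested genes, equal array medians, a variance trend with robust moderation, array weights, only the arrays of a comparison, the mean of a gene's clusters, all clusters without names, blocks for the replicate number and the array number, and each array left out in turn. Cyclic loess normalization and a fit without the 3 arrays with Prl above 10 were added after seeing the data. Plots were drawn with matplotlib 3.10.9.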

Results

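The series asked how the adaptive immune system affects amyloid disease in mouse brain, by crossing 5xfAD mice onto a background without T, B and NK cells. Whole-transcript arrays measured 22067 named genes in forebrain of 4 WT_WT, 4 WT_5xfAD, 4 Rag_WT and 4 Rag_5xfAD mice. In a principal component analysis, the first component held 37.2% of the variance and the second 19.5%.

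Rag2, the lymphocyte recombinase removed in the knockout, was dim in every group, at the 19.0th percentile of mean level. Its log2 value lay between 4.81 and 4.99 in WT_WT, 4.70 and 5.02 in WT_5xfAD, 5.06 and 5.30 in Rag_WT, and 5.05 and 5.16 in Rag_5xfAD. The arrays labelled Rag were thus not lower for Rag2. Where its probes lie relative to the deleted part is not given in the sources used here, so this cluster does not check the labels, and Il2rg was not analysed here. Thy1, whose promoter drives the transgenes, did follow the labels: it lay between 10.83 and 10.97 in WT_5xfAD against 10.34 to 10.47 in WT_WT, and between 10.86 and 11.03 in Rag_5xfAD against 10.30 to 10.55 in Rag_WT.

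The first comparison asked what the transgenes do when lymphocytes are present. Microglial and astrocytic genes rose in WT_5xfAD. Cst7, a cathepsin inhibitor of activated microglia, rose 8.08-fold, from 5.78 ± 0.11 to 8.80 ± 0.23 (SD, n = 4 and 4, adjusted p = 1.03e-11). Clec7a, a pattern recognition receptor, rose 7.69-fold (adjusted p = 1.68e-08), and Gfap, the intermediate filament of reactive astrocytes, rose by 2.03 on the log2 scale (adjusted p = 1.29e-09). Serpina3n, Olfr111, Lilrb4a, Lyz2 and C4b completed the largest rises, with log2 fold changes of 2.19, 2.07, 2.05, 1.95 and 1.94. Thy1 rose by 0.47 (SE 0.05, adjusted p = 3.12e-05), whereas App differed by 0.10 (SE 0.03, adjusted p = 0.0731).

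In all, limma called 1081 genes in WT_5xfAD against WT_WT, 984 higher and 97 lower, of which 34 rose and 1 fell at least 2-fold. Groups did not overlap for 14.7% of genes, against 2.86% by chance. Quantile normalization moved the split to 631 higher and 280 lower, cyclic loess to 638 and 182, and equal medians to 572 and 207. Without WT_5xfAD replicate 4 the count was 648, without WT_WT replicate 3 it was 686, and without WT_WT replicate 2 it was 717. The largest falls were in microRNA genes: Mir378c fell by 1.08, Mir329 by 0.77, Mir1197 by 0.69, Mir376b by 0.65 and Mir493 by 0.61 on the log2 scale. With the array number as a block, 671 genes were called. Mir493 lost its call in 7 of 28 alternatives (highest adjusted p = 0.0902), among them that block and the fits without WT_5xfAD replicate 1, 3 or 4 or WT_WT replicate 1, 2 or 3. Mir376b lost it in 5 of 28 (highest 0.0706), without WT_WT replicate 2 or 3 or WT_5xfAD replicate 2, 3 or 4, and Mir378c in 3 of 28 (highest 0.0726), without WT_5xfAD replicate 1 or 4 or the 3 arrays with Prl above 10.

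Disease-associated microglia genes rose in 25 of 29 measured members (28 adjusted over the list alone), with a median log2 fold change of 0.75, and none fell. Tyrobp, the signalling adaptor of Trem2, rose by 1.68 and Ccl3 by 1.71. Homeostatic microglia genes rose too, in 12 of 18 (14 adjusted over the list alone), among them Csf1r, the receptor that maintains microglia, by 0.73, Gpr34 by 0.77 and Cx3cr1 by 0.71. Of the lysosome genes 17 of 22 rose (20 adjusted over the list alone), with Ctss at 1.31 and Laptm5 at 1.12. Of the complement genes 10 of 13 rose (10 adjusted over the list alone), with C1qb at 1.30 and C1qa at 0.84. Fc receptor and phagocytosis genes rose in 12 of 20 (16 adjusted over the list alone), with Cd68 at 1.72, Fcgr2b at 1.29 and Trem2 at 1.26.

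Interferon response genes rose in 22 of 29 (26 adjusted over the list alone), with Ifi204 at 1.01 and Trim30a at 0.65. MHC class I genes rose in 9 of 13 (10 adjusted over the list alone), with H2-K1 at 0.70 and B2m at 0.58, and MHC class II genes in 4 of 12 (9 adjusted over the list alone), with the costimulatory gene Cd86 at 0.57. Reactive astrocyte genes rose in 11 of 22 (14 adjusted over the list alone), Osmr by 1.20 among them. Cytokine and chemokine genes rose in 9 of 26 (12 adjusted over the list alone), with Ccl6 at 1.02. These 10 lists passed camera and held with an estimated correlation, the largest adjusted p then being 0.0476 for the interferon list.

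Cholesterol synthesis genes rose in 10 of 15 (11 adjusted over the list alone), with Fdps at 0.41, Sqle at 0.38 and Stard4 at 0.37 (adjusted p = 0.0566 with an estimated correlation). Oligodendrocyte genes rose in 5 of 15 (12 adjusted over the list alone), with Trf at 0.48 and Cldn11 at 0.45 (adjusted p = 0.162 with an estimated correlation). NF-kB genes rose in 6 of 21 (9 alone), with Tlr7 at 0.88, and ribosomal protein genes in 5 of 8 (8 alone), with Rplp0 at 0.20 (adjusted p = 0.0582 with an estimated correlation for both). Astrocyte genes rose in 5 of 13 (6 alone), with Mlc1 at 0.33 (adjusted p = 0.16 with an estimated correlation). Amyloid processing genes rose in 6 of 21 (11 alone, 1 lower), with Apoe at 0.37 and Abca1 at 0.41 (adjusted p = 0.117 with an estimated correlation). Oligodendrocyte precursor genes rose in 2 of 13 (4 alone; adjusted p = 0.215 with an estimated correlation). Activity-regulated genes, 0 of 21 past the threshold in limma, and cerebellum genes, 0 of 12 (0 and 0 adjusted over the list alone), passed camera with medians of -0.04 and -0.05 (adjusted p = 0.696 and 0.34 with an estimated correlation). Without the 3 arrays with Prl above 10 both lost the call (camera adjusted p = 0.0833 and 0.0669), and the choroid plexus and pituitary lists passed (0.0241 and 0.0476). None of 21 neuron genes passed in limma, and that list did not pass camera (adjusted p = 0.758). Stmn2 differed by 0.18 (adjusted p = 0.0938).

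**Figure D1:**
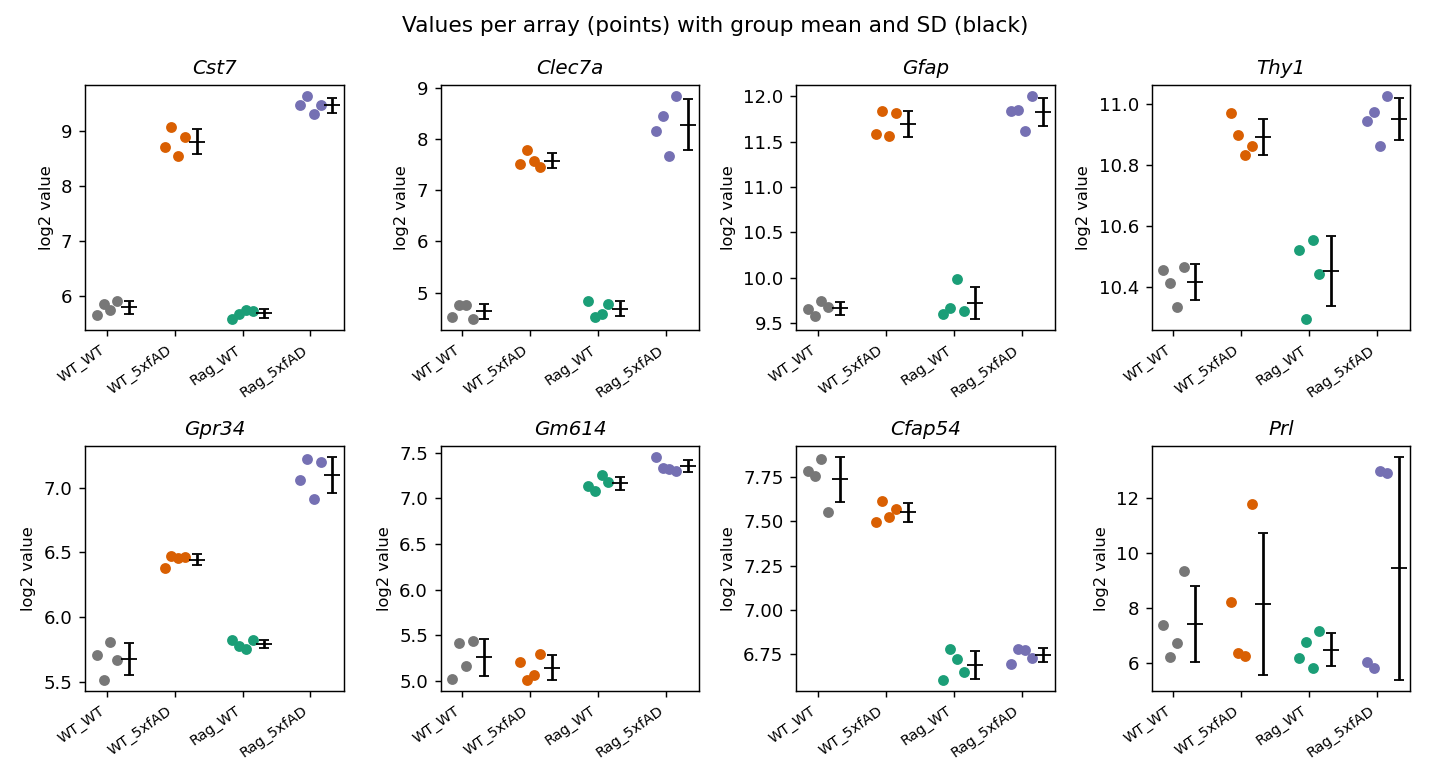
Log2 values per array of 8 genes in the 4 groups, with the group mean and SD in black. Cst7, Clec7a and Gfap separate both transgenic groups from the others, Gm614 and Cfap54 separate the arrays labelled Rag, and Prl, chosen after its values were seen, exceeds 10 on 3 arrays.

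The second comparison asked the same of immune-deficient mice. The same microglial genes led in Rag_5xfAD against Rag_WT. Cst7 rose 13.8-fold, from 5.67 ± 0.07 to 9.46 ± 0.14 (SD, n = 4 and 4, adjusted p = 2.66e-13), and Clec7a 12.1-fold (adjusted p = 7.02e-10). Lilrb4a, Serpina3n, Olfr111, Mpeg1, a macrophage pore-forming protein, Lyz2 and C4b rose by 2.46, 2.44, 2.41, 2.36, 2.32 and 2.31 on the log2 scale. Gfap rose by 2.10 and Thy1 by 0.50 (adjusted p = 9.65e-06), whereas App differed by 0.08 (adjusted p = 0.133) and Rag2 by -0.07 (adjusted p = 0.509). Rpe65 fell by 0.77, Mir7652 by 0.58, Klri1 by 0.43 and the neuropeptide gene Adcyap1 by 0.36. Mir7652 lost its call without Rag_WT replicate 1 or 4 or Rag_5xfAD replicate 2 (highest adjusted p = 0.0833), and Adcyap1 without the 3 arrays with Prl above 10 (0.0581).

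Limma called 1261 genes, 817 higher and 444 lower, of which 67 changed at least 2-fold, all of them higher. Groups did not overlap for 14.4% of genes, against 2.86% by chance. Cyclic loess moved the split to 943 higher and 175 lower, and equal medians to 916 and 839. Without Rag_5xfAD replicate 2 the count was 741, without Rag_WT replicate 1 it was 759, and without Rag_WT replicate 4 it was 762, with 114, 146 and 120 lower in place of 444. Over all fits with an array left out, the lower calls ran from 114 to 769, the latter without WT_WT replicate 1, and the higher calls from 613 to 884.

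Disease-associated microglia genes rose in 25 of 29 (26 adjusted over the list alone), median 0.95, with Tyrobp at 2.13. Homeostatic microglia genes rose in 14 of 18 (15 and 1 lower adjusted over the list alone), with Gpr34 at 1.30, Csf1r at 1.04 and Siglech at 0.98. Lysosome genes rose in 18 of 22 (19 alone), with Ctss at 1.67, complement genes in 9 of 13 (10 and 1 lower alone), with C1qb at 1.38 and Itgb2 at 1.14, and Fc receptor and phagocytosis genes in 14 of 20 (15 alone), with Cd68 at 2.15 and Fcgr2b at 1.74. Interferon genes rose in 23 of 29 (25 alone), with Ifi204 at 1.28, MHC class I genes in 8 of 13 (10 alone), with B2m at 0.80, and MHC class II genes in 5 of 12 (5 and 1 lower alone), with Cd86 at 0.80. Reactive astrocyte genes rose in 9 of 22 (13 and 1 lower alone), with Osmr at 1.52 and Vim at 0.99. Cytokine and chemokine genes rose in 11 of 26 (12 alone), with Ccl3 at 2.24 and Ccl12 at 1.25, NF-kB genes in 8 of 21 (10 and 1 lower alone), with Tlr7 at 1.45, cholesterol synthesis genes in 6 of 15 (11 alone), with Stard4 at 0.41, and ribosomal protein genes in 3 of 8 (7 alone), with Rps4x at 0.36. These 13 lists held with an estimated correlation, the largest adjusted p then being 0.0338.

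9 further lists lost their call with an estimated correlation. Fry passed 4 of these 9, the T cell, NK cell, astrocyte and amyloid processing lists. It compares a list with no change rather than with other genes, so a shift shared by many genes can also pass it. With an estimated correlation the adjusted p was 0.0518 for amyloid processing genes (4 of 21 rose, 7 adjusted over the list alone), 0.152 for astrocyte genes (3 of 13 rose, 5 alone, with Aqp4 at 0.40), 0.362 for oligodendrocyte genes (2 of 15 rose, 2 alone, with Trf at 0.50) and 0.372 for heat shock genes (1 of 15 rose, 1 alone). The striatum list, 0 of 9 past the threshold in limma (0 adjusted over the list alone) and with a median of 0.21, had 0.541. T cell, NK cell, activity-regulated and endothelial genes had negative medians and 0.372, 0.368, 0.54 and 0.471. Across genes, the log2 fold change rose with mean level in this comparison (Spearman 0.419), with a median of -0.08 for dim genes other than receptor genes and -0.06 for receptor genes. Of the T cell, NK cell, activity-regulated and endothelial genes, 0 of 14, 2 of 14, 1 of 21 and 1 of 15 fell (6, 4, 1 and 2 adjusted over the list alone), namely Nkg7 by 0.29, Il2rb by 0.20, Egr4 by 0.27 and Esam by 0.14. Each of these calls ended in some alternatives. Esam lost it in 8 of 27 (highest adjusted p = 0.0841), among them cyclic loess, the array number block and the fits without Rag_5xfAD replicate 1 or 2 or Rag_WT replicate 1, 3 or 4. Egr4 lost it in 5 of 28 (highest 0.0734), among them without Rag_5xfAD replicate 1 or 2 or Rag_WT replicate 4, Nkg7 in 4 of 27 (highest 0.0584), without Rag_5xfAD replicate 1 or 2 or Rag_WT replicate 1 or 4, and Il2rb in 3 of 27 (highest 0.0671), among them without Rag_5xfAD replicate 2 or Rag_WT replicate 4. The hypothalamus and pituitary list did not pass (camera adjusted p = 0.58). The border macrophage, neutrophil, choroid plexus, cerebellum, mural cell, precursor, neuron and B cell lists did not pass, with camera adjusted p of 0.167, 0.176, 0.296, 0.266, 0.144, 0.0637, 0.486 and 0.19. Without the 3 arrays with Prl above 10, the hypothalamus and pituitary, border macrophage and mural cell lists passed (camera adjusted p = 0.0166, 0.00517 and 0.00278), while the activity-regulated, endothelial, striatum and heat shock lists did not (0.272, 0.142, 0.119 and 0.119).

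Across genes, which are not independent replicates, the log2 fold changes of both transgene comparisons had a Pearson r of 0.673, and the comparisons share no arrays. Of the called genes, 556 were higher in both, against 36.4 for independent lists, with 476 after quantile normalization and 497 after cyclic loess. As deposited, 425 of the 556 had the larger change in immune-deficient mice. The median log2 fold change of the 556 was 0.34 in immune-competent and 0.41 in immune-deficient mice. Over genes called in either, the regression slope of the immune-deficient on the immune-competent change was 1.19 as deposited. It was 1.11 after quantile normalization and 1.14 after cyclic loess.

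**Figure D2:**
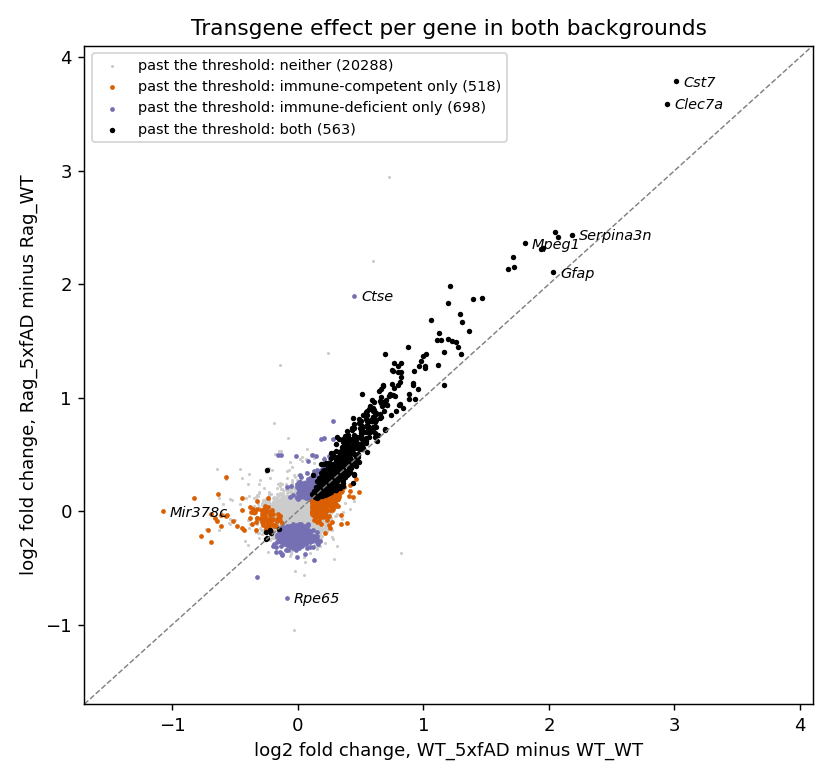
Log2 fold change of each gene in WT_5xfAD minus WT_WT (horizontal axis) against Rag_5xfAD minus Rag_WT (vertical axis), coloured by which comparison passed, with the line of equal change dashed. Cst7, at 3.02 and 3.79, and Clec7a, at 2.94 and 3.59, lie above the line.

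The third comparison asked what immune deficiency does without amyloid. Few genes differed, and lymphocyte genes were not among them. Gm614, a gene of unassigned function that neighbours Il2rg, rose 3.74-fold in Rag_WT, from 5.26 ± 0.20 to 7.16 ± 0.07 (SD, n = 4 and 4, adjusted p = 2.22e-09). A330049N07Rik rose by 1.25 on the log2 scale, and Aldh7a1, a lysine-degrading dehydrogenase, by 0.58. Mir1931 fell by 1.58, Cfap54, a ciliary gene of the same locus, by 1.05, and Pcdhb6, a protocadherin, fell to 0.5 times its WT_WT level.

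Limma called 19 genes, 12 higher and 7 lower, against 18 and 6 after quantile normalization and 23 and 6 after cyclic loess, which raised the share of higher calls from 63.2% to 75% and 79.3%. Without WT_WT replicate 1 the count was 139. Pisd-ps3, Pisd-ps1 and Pisd-ps2, pseudogenes of one family, rose by 0.65, 0.53 and 0.50, Ddx4 by 0.48 and Slc38a9 by 0.36. Whether the Pisd-ps clusters share probes was not checked, so their signals may not be separate. Ppwd1, Cd59b, Gm8615 and Cd5l fell by 0.60, 0.38, 0.38 and 0.20. Cd5l lost its call in 11 of 27 alternatives (highest adjusted p = 0.209), among them both further normalizations and the fits without WT_WT replicate 2, 3 or 4 or Rag_WT replicate 2, 3 or 4. Ddx4 lost it in 7 of 26 (highest 0.123), among them the fits without Rag_WT replicate 1, 3 or 4, WT_WT replicate 2 or 4, or the 3 arrays with Prl above 10. Rag2 differed by 0.30 (adjusted p = 0.109; 0.0317 after quantile normalization), App by 0.03 (adjusted p = 0.691) and Thy1 by 0.04 (adjusted p = 0.762).

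Of the 14 T cell, 9 B cell and 14 NK cell genes measured, 0 passed in limma (0, 0 and 1 adjusted over the list alone), at medians of -0.09, -0.10 and -0.05. Across genes, the log2 fold change rose with mean level here too (Spearman 0.497), and dim genes other than receptor genes had a median of -0.05. At an unadjusted p under 0.05 the comparison held 3013 genes. Cd3g differed by -0.15 (adjusted p = 0.291), Cd79b by -0.15 (0.291) and Ifng by -0.15 (0.244). These lists and 9 others passed camera, but 0 of the 12 held with an estimated correlation, where the smallest adjusted p was 0.551, or with fry. No member of the other 9 passed in limma over all genes, and adjusted over the list alone 2 cholesterol synthesis, 1 mitochondrial and 1 ribosomal gene passed, beside the oligodendrocyte genes below, and 0 of the other 5 lists. The oligodendrocyte list (median 0.14, 4 of 15 adjusted over the list alone, adjusted p = 0.551 with an estimated correlation) had Opalin at 0.54 (adjusted p = 0.0868) and Mog at 0.21. The mitochondrial, ribosomal, cholesterol synthesis, endothelial, neuron, activity-regulated and lysosome lists had medians of 0.08, 0.08, 0.08, 0.07, 0.04, 0.05 and 0.06, and MHC class II -0.08. Cox5a differed by 0.19, Rpl27 by 0.21, Insig1 by 0.18, Itm2a by 0.16, Dusp1 by 0.55 and Fos by 0.42, none past the threshold. Among the neighbours of Rag2 and Il2rg, Fjx1 differed by 0.17 (adjusted p = 0.248) and Cxcr3 by -0.17 (adjusted p = 0.183), and both neighbour lists missed the threshold (camera adjusted p = 0.107 and 0.398). Of the called genes, however, Gm614 lies next to Il2rg and Cd59b 22 genes from Rag2.

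The fourth comparison, the question of the series title, set Rag_5xfAD against WT_5xfAD. Some microglial genes were higher in Rag_5xfAD, 10 of 18 homeostatic and 12 of 29 disease-associated list members, though neither list held with an estimated correlation (adjusted p = 0.105 and 0.33). Gpr34, a microglial lysophospholipid receptor, rose 1.57-fold, from 6.44 ± 0.04 to 7.10 ± 0.14 (SD, n = 4 and 4, adjusted p = 7.22e-05). Cst7 rose 1.58-fold, Lyz2 1.59-fold and Tgfbr1, a receptor for a cytokine that maintains microglia, 1.35-fold (adjusted p = 0.0014, 0.00221 and 0.000311). The lymphocyte genes Cd3g, Cd8a and Cd3e fell by 0.30, 0.35 and 0.35 (-0.16, -0.21 and -0.21 after quantile normalization), and among 10 equal bins of genes by level, the bin at a mean level of 5.44 had a median of -0.15 in this comparison.

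Limma called 7651 genes, 1721 higher and 5930 lower, and only 4 rose and 2 fell at least 2-fold. Quantile normalization gave 1791 higher and 1672 lower, cyclic loess 2183 and 1339, and equal medians 3220 and 2537. Groups did not overlap for 32.4% of genes, against 2.86% by chance. Across genes, the log2 fold change rose with mean level (Spearman 0.476), and Rag_5xfAD arrays had a wider distribution than WT_5xfAD arrays, as their interquartile ranges show. Without WT_5xfAD replicate 1 the count was 4478, without Rag_5xfAD replicate 2 it was 4664, and without the 3 arrays with Prl above 10 it was 4333. Gm614 rose by 2.21, A330049N07Rik by 1.44, Ctse by 1.42, Scarna9 by 1.01, Mir684-2 by 0.94, Snord98 by 0.87 and Olfr110 by 0.86. Cd59a fell by 1.07, Mir1931 by 1.02, Cfap54 by 0.81, Pcdhb6 by 0.78, Mir363 by 0.56 and Aox4 by 0.52. Rag2, dim in all groups, rose by 0.27 (adjusted p = 0.0084; 0.0900 without the 3 arrays with Prl above 10), while App differed by 0.00 (adjusted p = 0.916; -0.06 after quantile normalization) and Thy1 by 0.06 (adjusted p = 0.387).

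**Figure D3:**
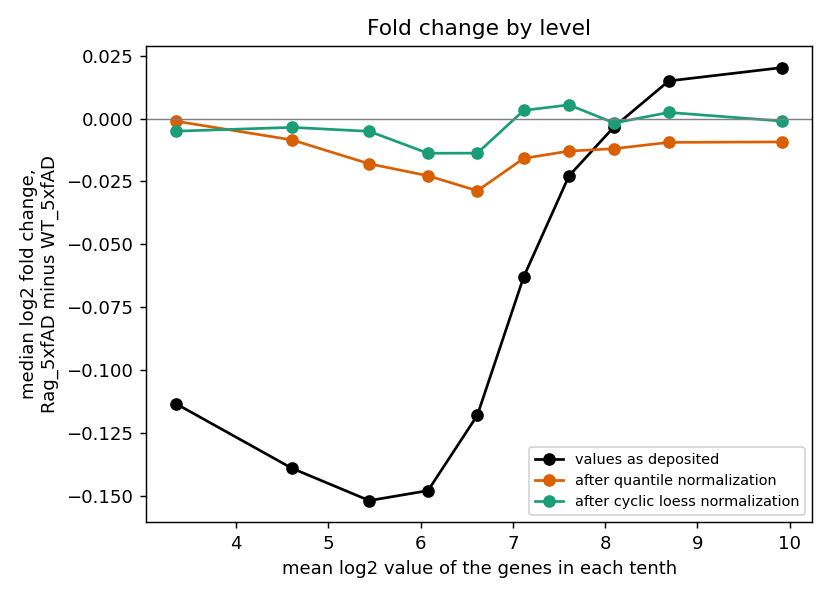
Median log2 fold change of Rag_5xfAD minus WT_5xfAD (vertical axis) over 10 equal bins of genes by mean log2 value (horizontal axis), for the values as deposited and after both further normalizations. The deposited medians run from -0.15 in the bin at 5.44 to 0.02 in the brightest bin, at 9.92.

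Homeostatic microglia genes rose in 10 of 18 and fell in 1 (10 and 1 adjusted over the list alone), with Csf1r at 0.39 and Siglech at 0.40 (adjusted p = 0.105 with an estimated correlation). Disease-associated microglia genes rose in 12 of 29 and fell in 1 (17 and 1 alone), with Tyrobp at 0.55 and Lpl at 0.29, and lysosome genes rose in 12 of 22 (15 and 1 lower alone), with Ctss at 0.48, Hexa at 0.34 and Ctsh at 0.32 (adjusted p = 0.33 with an estimated correlation for both). Fc receptor genes rose in 5 of 20 and fell in 1 (5 and 1 alone), Cd68 by 0.44 and Fcgr2b by 0.41 against Fcgrt, which fell by 0.20. Complement genes rose in 3 of 13 and fell in 1 (3 and 1 alone), with Itgb2 at 0.36, Itgam at 0.40 and C4b at 0.39 against C2, which fell by 0.22 (adjusted p = 0.452 with an estimated correlation for both lists). The fall of C2 did not pass in 6 of 27 alternatives, among them quantile normalization (-0.09), cyclic loess (highest adjusted p = 0.251) and the fits without Rag_5xfAD replicate 1 or 2 or WT_5xfAD replicate 4. Fcgrt lost its call in 5 of 28 (highest 0.118), among them without Rag_5xfAD replicate 2 or WT_5xfAD replicate 1 or 4, and Fcgr2b in 3 of 28 (highest 0.0556), among them without Rag_5xfAD replicate 1 or WT_5xfAD replicate 1.

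T cell genes fell in 13 of 14 (13 alone), B cell genes in 7 of 9 (8 alone) and NK cell genes in 7 of 14 (10 alone), against 5, 0 and 2 after quantile normalization (adjusted p = 0.462, 0.463 and 0.463 with an estimated correlation). In the same comparison 42.8% of dim genes other than receptor genes and 26.5% of receptor genes were called lower. The list members were not compared with genes of like level. Cd79a fell by 0.22, Ms4a1 by 0.20, Il2rb by 0.28 and Nkg7 by 0.35. After quantile normalization Il2rb differed by -0.15 and Nkg7 by -0.23, and Cd79a and Ms4a1 did not pass. Il2rb and Nkg7 also fell in Rag_5xfAD against Rag_WT, where both groups lack NK cells. Border macrophage genes fell in 9 of 14 (9 alone), with Stab1 and Lyve1 at -0.22, against 3 after quantile normalization (adjusted p = 0.463 with an estimated correlation). Cholesterol synthesis, mitochondrial and ribosomal genes rose in 2 of 15, 3 of 20 and 3 of 8, (1, 3 and 3 adjusted over the list alone), with Idi1 at 0.37, Atp5l at 0.21 and Rps4x at 0.24 (adjusted p = 0.463, 0.462 and 0.462 with an estimated correlation). NF-kB genes rose in 4 of 21 and fell in 4 (4 and 4 alone), with Tlr7 at 0.57, and interferon genes rose in 3 of 29 and fell in 1, though 0 passed in limma adjusted over the list alone (adjusted p = 0.463 and 0.737 with an estimated correlation). Amyloid processing genes rose in 4 of 21 and fell in 1 (4 and 1 alone), oligodendrocyte genes rose in 1 of 15 (0 alone), and the striatum list, with 0 of 9 past the threshold in limma (0 alone), had a median of 0.25 (adjusted p = 0.462, 0.635 and 0.62 with an estimated correlation). These 17 lists passed camera, and 0 held with an estimated correlation. Fry passed 9 lists, among them MHC class II and mural cell genes, which camera did not. Without the 3 arrays with Prl above 10, camera passed the mural cell, cytokine and activity-regulated lists (adjusted p = 0.00544, 0.0197 and 0.0445). The medians of the astrocyte, reactive astrocyte, precursor, neuron, activity-regulated, neutrophil, cytokine, choroid plexus, pituitary and heat shock lists were below 0 while camera put them up, none past the threshold. Lists that did not pass held Ciita at -0.21, Cd86 at 0.20, Osmr at 0.46, Csf3r at 0.39, Slc6a13 at -0.37, Cxcr3 at -0.25, Taf1 at 0.16 and Alx4 at -0.31, all past the threshold, and Pomc at 1.40 (adjusted p = 0.0656). Pomc stood at 8.95 and 7.86 in Rag_5xfAD replicates 3 and 4 against 5.27 and 5.30 in replicates 1 and 2, and differed by -0.17 without the 3 arrays with Prl above 10 (adjusted p = 0.238). Cxcr3 differed by -0.11 and Alx4 by -0.18 after quantile normalization. Ciita and Lyve1 did not pass after quantile normalization.

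Across genes, the immune deficiency effects with and without transgene had a Pearson r of 0.570, and 0.450 to 0.632 with each array left out. It was 0.467 after quantile normalization and 0.460 after cyclic loess. Both effects rose with mean level as deposited (Spearman 0.497 and 0.476), and how much of r goes with that was not tested. All 12 higher and 7 lower genes of the comparison without transgene were called in the same direction with it, against 0.936 and 1.88 for independent lists. The shared counts were 15 and 6 after quantile normalization and 20 and 6 after cyclic loess.

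**Figure D4:**
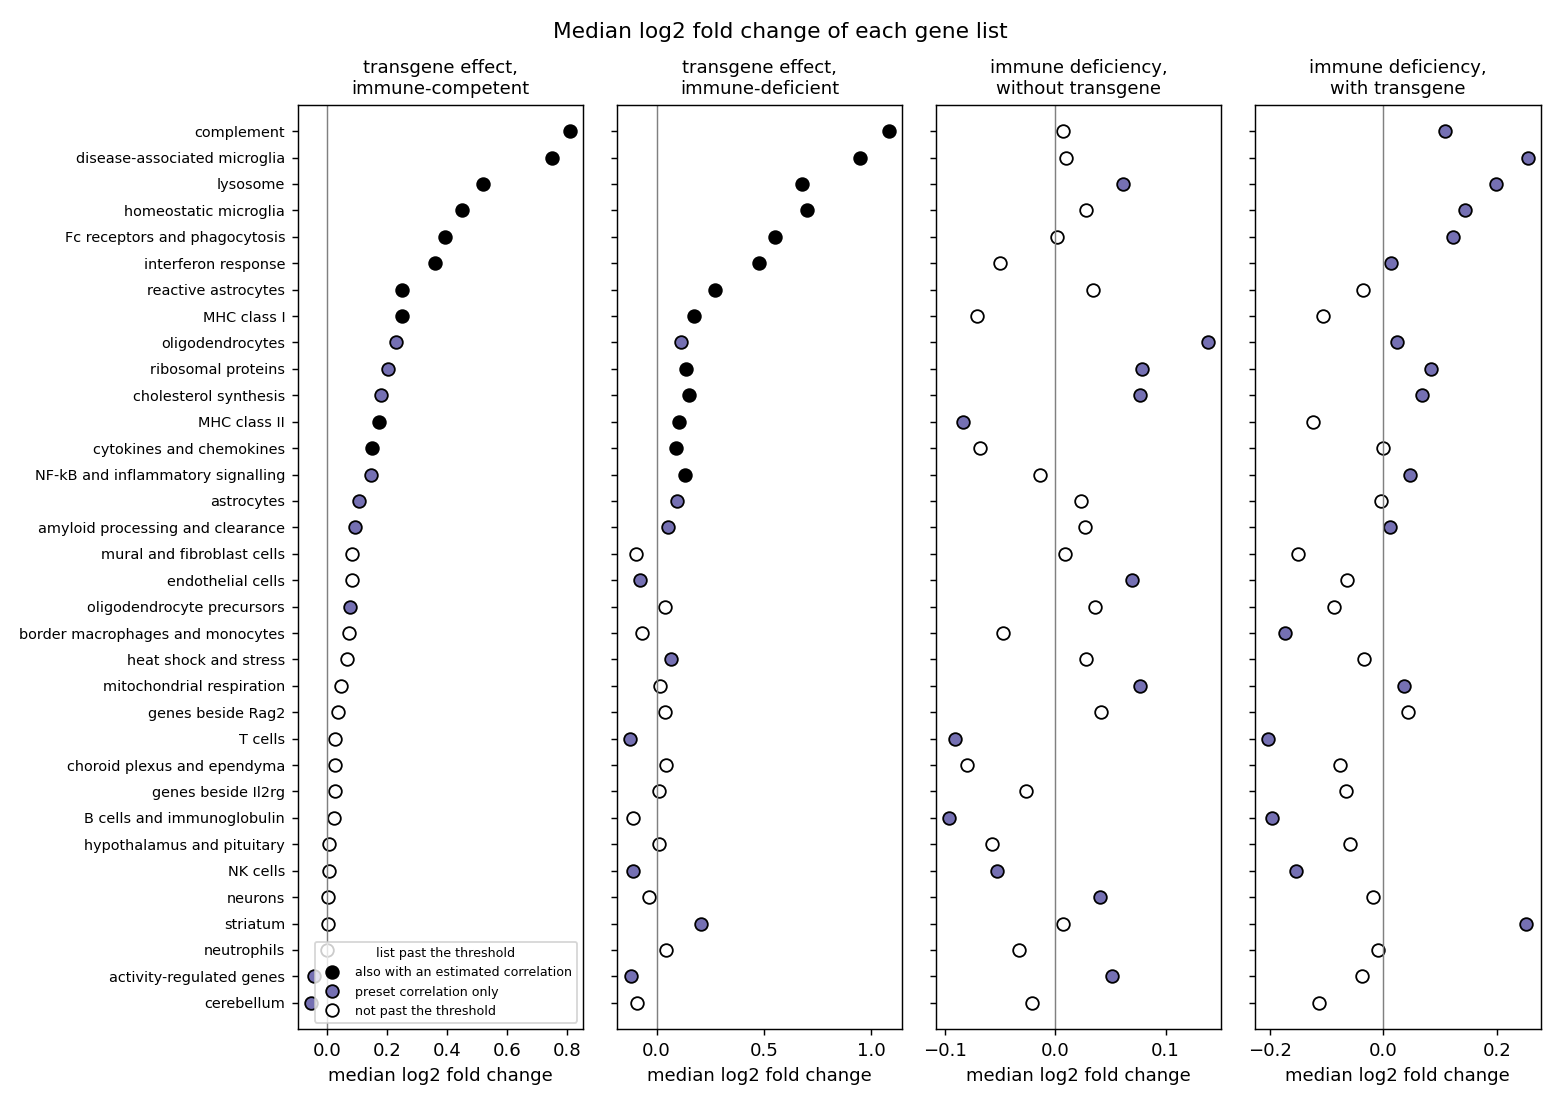
Median log2 fold change of each tested gene list (horizontal axes) in the 4 comparisons of groups. Points are black where camera passed also with an estimated correlation, purple where only with the preset one and open where it did not pass, and the homeostatic microglia list lies at 0.45, 0.70, 0.03 and 0.14, from left to right.

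The interaction tested whether the transgene effect differed between backgrounds. No single gene passed in limma, and of the microglial lists the homeostatic one held with camera, an estimated correlation and fry while the disease-associated one lost its call (adjusted p = 0.192 with an estimated correlation; 0.2 with fry). The homeostatic microglia list had a median interaction of 0.17 with 15 of 18 members above 0 (camera adjusted p = 2.85e-13; adjusted p = 0.0185 with an estimated correlation; 0.0277 with fry). Gpr34 differed by 0.54 (SE 0.09, adjusted p = 0.144), Tgfbr1 by 0.39, Siglech by 0.39 and Csf1r by 0.30. Of its members 0 passed over all genes and 7 adjusted over the list alone.

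Limma called 0 genes for the interaction, with 2998 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0779, shared by Mir703 (0.60) and Aox4 (-0.50). Leaving out Rag_5xfAD replicate 3 gave 14 genes, WT_WT replicate 2 gave 2, and Rag_5xfAD replicate 2, Rag_WT replicate 2, WT_5xfAD replicate 2 and WT_5xfAD replicate 4 gave 1 each, and leaving out the 3 arrays with Prl above 10 gave 8. The other values given by rule were 0.77 for Cst7, -0.41 for Olfr796, -0.33 for Tktl2, -0.02 for Rag2 (adjusted p = 0.911), -0.02 for App (0.825) and 0.02 for Thy1 (0.891), where Rag2 turned positive after both further normalizations. The disease-associated list had a median of 0.15 with Cst7 and Tyrobp (0.45) among its members, and the lysosome list 0.14 with Ctss at 0.36, with 4 and 0 members adjusted over the list alone in limma, and both lost the call (adjusted p = 0.192 with an estimated correlation). Fc receptor genes, with Cd68 at 0.43, complement genes, with Itgb2 at 0.32, and cytokine genes did so at the same adjusted p of 0.192. NF-kB genes, with Tlr7 at 0.57, interferon, striatum, endothelial (Itm2a at -0.24), T cell, border macrophage and mural cell genes made up the 13 lists past camera. Adjusted over the list alone, 2 complement, 2 cytokine, 1 NF-kB, 3 border macrophage and 3 mural cell genes passed, and 0 of the Fc receptor, interferon, striatum, endothelial and T cell lists. Of the 13 lists, only the homeostatic one held with an estimated correlation or with fry. With an estimated correlation the adjusted p was 0.553 for the NF-kB, endothelial and mural lists, 0.581 for interferon, and 0.626 for the striatum, T cell and border macrophage lists. Without the 3 arrays with Prl above 10 the endothelial list lost its call (camera adjusted p = 0.0725), and the amyloid processing and cholesterol synthesis lists passed (0.0363 and 0.0323). The striatum list had a median interaction of 0.25 and the T cell list of -0.15.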

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

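The split counts, the test on receptor genes, and the tests of pituitary RNA and of microglial composition for the interaction were fixed before their results were seen, and all other tests here were chosen after.

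Among 383 sets of 4 arrays, one per gene and group, 15 had an array set far apart from the other 3 by Dixon's test, against 19.2 by chance, which marks about 1 in 20. The widest gap was in S100a8, a neutrophil gene chosen after its values were seen, at 7.57 in Rag_5xfAD replicate 4 against 3.72 to 4.05 in the others. The pituitary genes Cga and Gh were chosen after their values were seen. Cga was highest of its group at 6.74 in WT_5xfAD replicate 4 and at 6.26 in Rag_WT replicate 2. Gh was lowest of its group at 6.53 in Rag_WT replicate 3, against 7.01 to 7.09 in the others. Among microglial and lipid genes, Apoe was lowest of its group at 10.50 in WT_WT replicate 2 and Cd68 at 7.70 in WT_WT replicate 1. Gpr34 was lowest at 6.38 in WT_5xfAD replicate 1, whereas Ccl12 was highest at 4.78 in Rag_WT replicate 3. Gm614 was highest at 7.46 and Rbfox3 at 10.11 in Rag_5xfAD replicate 1, and Mir703 at 10.36 in Rag_5xfAD replicate 4. Slc6a13 was lowest at 7.04 in Rag_5xfAD replicate 2 and Trf at 11.49 in Rag_5xfAD replicate 3. Mir1931 was lowest at 7.44 in WT_5xfAD replicate 1 and Pisd-ps1 at 8.33 in WT_WT replicate 3.

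The transgene effect differed between backgrounds for 13 lists by camera on the interaction. Upward, the adjusted p was 1.07e-14 for disease-associated microglia, 2.85e-13 for homeostatic microglia, 5.92e-10 for lysosome, 1.73e-06 for Fc receptor, 5.97e-06 for interferon, 2.50e-05 for complement, 0.000413 for cytokine, 0.00420 for NF-kB and 0.00420 for striatum genes. Downward, it was 0.00420 for endothelial, 0.0107 for T cell, 0.0273 for border macrophage and 0.0294 for mural cell genes. Only the homeostatic list held with an estimated correlation.

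Other splits of the arrays were counted for each result. Chance alone is argued against for the gene counts of the 4 comparisons of groups, where 1 of 35 splits, the real one, gave as many genes: 1081 against a highest other of 1, 1261 against 2, 19 against 10, and 7651 against 3. That is the smallest share possible, and the other splits mix the groups, so a real difference lowers their counts. The splits cannot separate genotype from another difference between arrays that goes with the groups, such as one in level or array number. Chance stays open for the list counts, where 6 of 35 splits gave at least 19 lists (highest other 21), 8 of 35 at least 22 (25), 3 of 35 at least 12 (13) and 5 of 35 at least 17 (24). For the interaction, limma called 0 genes (2998 at an unadjusted p under 0.05), which all 100 of 100 drawn splits reach by construction, so that count says nothing about chance. The highest other, 1171, points to a structure of the samples, which includes the group differences themselves, since the drawn splits mix the groups, and 44 of 100 gave at least 13 lists (highest other 24). Chance alone is argued against for the agreement of the transgene effects, with 1 of 100 splits at or above 0.673 (highest other 0.608). It is less so for the immune deficiency effects, with 3 of 100 at or above 0.570 (highest other 0.651). These splits used the deposited values only, and the r of the immune deficiency effects was 0.467 after quantile normalization and 0.460 after cyclic loess.

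More genes were lower than higher in Rag_5xfAD against WT_5xfAD. RNA from pituitary as the whole cause is argued against, since 80.6% of calls were lower without the 3 arrays with Prl above 10, against 77.5% with them. A level-dependent difference between arrays is a candidate explanation: the 1395 olfactory and vomeronasal receptor genes, not known to be used as a class in forebrain, had a median of -0.13, as had the other dim genes, against -0.01 for bright genes. After quantile normalization the receptor median was -0.02. A biological loss of dim transcripts was not tested apart from this and stays open.

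The 19 genes that differed between Rag_WT and WT_WT separated all 8 arrays labelled Rag from the other 8. Loss of lymphocyte RNA is argued against for the 12 of the 19 that were higher in Rag_WT. Of 37 lymphocyte list members 0 passed in limma (3013 genes at an unadjusted p under 0.05), so the 7 lower genes held no list member. That does not exclude a loss of lymphocyte RNA too small to pass. Chromosome segments inherited with the knockout alleles or from another strain may account for part: 6 of 16 placed genes outside the Pisd family had another within 50 genes in the GRCm38.p6 order, against a mean of 1.03 and a highest of 8 in 10000 random lists (permutation p = 0.0089). This stays open, because without Mir1931, of the same locus as Cfap54, it was 4 of 15 (permutation p = 0.0626), and leaving out Mir1931 and reading both together were chosen after the first result. The 4 genes left with a neighbour were Ddx4, Slc38a9, Ppwd1 and Nnt, the last named after its value was seen. Ddx4 lost its own call in 7 of 26 alternatives. Gm614 lies next to Il2rg and Cd59b 22 genes from Rag2. Within 50 genes of Rag2 lay 1 called gene, and within 50 of Il2rg 1. Random lists had a mean of 0.144 near either, and 0.83% of them held as many. This covers only Gm614 and Cd59b, and Gm614 had already been named for its rise.

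The transgene effect on the homeostatic microglia list was larger in immune-deficient mice, whereas the disease-associated list lost that call (adjusted p = 0.192 with an estimated correlation). A level-dependent difference as the whole cause is argued against, since the median interaction of the homeostatic list stayed above that of all genes after cyclic loess. The medians were 0.21 against 0.001 then, and 0.17 against -0.055 as deposited. The rise from 0.17 to 0.21 is no evidence by itself, since cyclic loess also raised the median of all genes. Pituitary RNA is argued against too, since the list's median was 0.21 without the 3 arrays with Prl above 10 (camera adjusted p = 4.27e-13). More microglia of unaltered state may account for it: the disease-associated minus the homeostatic mean differed by 0.06 between Rag_5xfAD and WT_5xfAD (n = 4 and 4, two-sided exact permutation p = 0.314). This p does not show that the means did not differ, so that explanation and a change of microglial state cannot be told apart. The homeostatic mean itself was higher by 0.18 (exact p = 0.0286, the smallest possible) and the disease-associated mean by 0.25 (exact p = 0.0857). The array number goes with the interaction too. In the first block of array numbers lie 3 of 4 Rag_5xfAD and 3 of 4 WT_WT arrays, but 1 of 4 Rag_WT and 1 of 4 WT_5xfAD arrays. The homeostatic list kept its call in all 29 alternatives, that block among them (highest adjusted p = 0.0277, with fry). Its median with the block is not given here, so a part that goes with array order stays open.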

How the results depend on the processing

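Cyclic loess and leaving out the 3 arrays with Prl above 10 were chosen after the results were seen. Where an alternative moved a value the cause was not tested, except that fewer genes or arrays entered by construction. Signal over background was not analysed here, and the number of arrays limits the precision.

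For WT_5xfAD against WT_WT, 2852 genes passed with array weights, 671 with the array number as a block, 666 without the Prl arrays, and 648 to 1236 with each array left out, the counts off by most being 717 without WT_WT replicate 2, 686 without WT_WT replicate 3 and 648 without WT_5xfAD replicate 4. With an estimated correlation 10 lists passed. For Rag_5xfAD against Rag_WT, 681 genes passed above the median level and 741 to 1653 with each array left out (741 without Rag_5xfAD replicate 2, 759 without Rag_WT replicate 1, 762 without Rag_WT replicate 4), and 13 lists passed with an estimated correlation.

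For Rag_WT against WT_WT, 31 genes passed above the median level, 34 above the 25th percentile, 34 with a variance trend and robust moderation, 95 with array weights, 29 after cyclic loess, and 15 to 139 with each array left out, 139 being without WT_WT replicate 1. There 3 lists passed above the median level, 6 after quantile normalization, 3 after cyclic loess, and 0 with an estimated correlation or with fry, beside 3013 genes at an unadjusted p under 0.05 in limma. For Rag_5xfAD against WT_5xfAD, 2816 genes passed above the median level, 3463 after quantile normalization, 3522 after cyclic loess, 4333 without the Prl arrays, and 4478 to 8149 with each array left out (4478 without WT_5xfAD replicate 1, 4664 without Rag_5xfAD replicate 2). There 5 lists passed above the median level, 11 above the 25th percentile, 9 after quantile normalization, 11 after cyclic loess, 9 with fry and 0 with an estimated correlation, beside 10410 genes at an unadjusted p under 0.05 in limma. For the interaction, 1 gene passed above the median level, 3 with array weights, 1 with the array number as a block, 8 without the Prl arrays, and 0 to 14 with each array left out, 14 being without Rag_5xfAD replicate 3. There 8 lists passed above the median level and 1 each with an estimated correlation and with fry.

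Reversed signs concerned values near 0 and Pomc. Rag2 differed by 0.012 after cyclic loess for Rag_5xfAD against Rag_WT. For Rag_WT against WT_WT, App differed by -0.0091 after cyclic loess, and Thy1 by -0.0081 after quantile normalization and -0.0042 after cyclic loess. App: immune deficiency, with transgene (Rag_5xfAD against WT_5xfAD) turned in 7 of 28 alternatives and Rag2 in 6 of 25 for the interaction. App was -0.062 after quantile normalization, -0.0038 with array weights, -0.000311 with the array number as a block, -0.017 after cyclic loess and -0.0097 to 0.0147 with each array left out. In the same comparison Pomc differed by -0.17 without the Prl arrays. In the interaction, Rag2 was 0.043 after quantile normalization, 0.020 with equal medians, 0.032 with the array number as a block, 0.055 after cyclic loess and -0.066 to 0.041 with each array left out, App was 0.023 with equal medians, and Thy1 was -0.030 with array weights and -0.028 to 0.058 with each array left out. The NF-kB list turned down for Rag_5xfAD against WT_5xfAD above the median level (adjusted p = 0.982).

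With the replicate number as a block, 1055, 1230, 18, 7673 and 0 genes passed in limma and 19, 22, 13, 17 and 13 lists, in the order of the comparisons, the 0 being the interaction, which had 2998 at an unadjusted p under 0.05 without the block. The numbers do not pair the samples: of 24 pairs with the same number, correlations of deviations ran from -0.281 to 0.312, 9 were above 0.1, and 5 of 16 arrays correlated best with their own number.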

Other observations

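All genes and tests in this part were chosen after their values were seen.

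Prl, the prolactin gene, was highest on 3 arrays, at 12.98 in Rag_5xfAD replicate 3, 12.89 in Rag_5xfAD replicate 4 and 11.77 in WT_5xfAD replicate 4, and Gh, the growth hormone gene, at 12.16, 11.50 and 10.54 on the same arrays. Pomc stood at 8.95, 7.86 and 5.42 there, the last being below 5.74 in Rag_WT replicate 2. The next highest for Prl and Gh were WT_WT replicate 4, with Prl at 9.36 and Gh at 8.17, and WT_5xfAD replicate 1, with 8.23 and 7.83, and the fit without the 3 arrays keeps both. The hypothalamic peptide genes Pmch and Hcrt stood at 9.78 and 9.24 in Rag_WT replicate 1 and at 9.31 and 8.03 in Rag_5xfAD replicate 2, while Pmch was lowest, at 5.05, in Rag_5xfAD replicate 1.

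MicroRNA genes of one cluster, 42 genes from Mir673 to Mir409 in the GRCm38.p6 order, lay lower in WT_5xfAD than in WT_WT. Their median log2 fold change was -0.31, 40 were below 0 and 6 fell past the threshold of limma, whereas 515 other microRNA genes had a median of -0.06. In Rag_WT against WT_WT, where no transgene differs, the cluster's median was -0.18 with 39 below 0 and 0 past the threshold of limma (3013 genes at an unadjusted p under 0.05), and in Rag_5xfAD against Rag_WT it was -0.08. In Rag_5xfAD against WT_5xfAD it was 0.06, with 4 genes higher and 3 lower past the threshold and -0.08 for the other microRNA genes, and for the interaction 0.24, both at a permutation p of 1e-04 for a median as high. A median as low occurred in random lists of other microRNA genes at a permutation p of 1e-04, the smallest possible, in both WT_5xfAD and Rag_WT against WT_WT. For WT_5xfAD this decides nothing about a lower signal of microRNA genes in general, since 4 of the cluster's genes were already named for their fall there. Rag_WT against WT_WT, Rag_5xfAD against WT_5xfAD and the interaction reuse the WT_WT or WT_5xfAD arrays on which the cluster was chosen. Their permutation p-values are therefore not independent of that choice and decide nothing either. None of these values takes the array number into account.

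The cluster mean was 7.02 ± 0.10 in WT_WT, 6.69 ± 0.07 in WT_5xfAD, 6.83 ± 0.14 in Rag_WT and 6.78 ± 0.18 in Rag_5xfAD (SD, n = 4 each). It also differed with the array number: in every group it was lower on arrays numbered 9 to 16 than on arrays 1 to 8, a difference of -0.21 (SE 0.04) with group as a term, and 3 of 4 WT_WT arrays lie in the first block against 1 of 4 WT_5xfAD arrays. The difference between WT_5xfAD and WT_WT was -0.33 without the block, -0.23 (SE 0.06) with it, -0.32 within the first block and -0.22 within the second, each of which holds 1 array of one of the groups. The other groups are as uneven, with 1 Rag_WT and 3 Rag_5xfAD arrays in the first block. With the block, the difference was -0.09 (SE 0.06) for Rag_WT against WT_WT, -0.16 (SE 0.06) for Rag_5xfAD against Rag_WT, -0.02 (SE 0.06) for Rag_5xfAD against WT_5xfAD and 0.07 (SE 0.09) for the interaction, against -0.19, -0.05, 0.09 and 0.28 without it.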
